A study of Oryza sativa with 9 samples.

How the data were processed

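RNA was sequenced from shoots of rice seedlings in the ZH11 background at the stage of 4 leaves, after 2 d at 4 °C. There were 9 libraries in 3 groups of 3: wild type (WT), an ossro1c mutant and an osdreb2b mutant. Every library came from chilled plants, so the comparisons describe differences between genotypes in the cold and not the response to cold. RNA was extracted with TRIzol and libraries were made with a SMARTER mRNA kit, per the labels. The deposited values are raw counts per locus, not normalised, with rice locus identifiers of the LOC_Os form. The submitters' processing notes name fastp 0.23.4, HISAT2 2.2.1, StringTie 2.1.4 and DESeq2, without giving the role or order of each. The genome build and annotation behind the counts are not given in the sources used here. Groups were read from the genotype labels, and the file held 0 columns that were left unused. The labels do not say that replicates are separate plants or separate pools, so p-values measure only the spread between these samples.

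The count table held 55801 loci. Library totals ran from 58398026 to 69336224 counts. Genes were kept by edgeR's filterByExpr with the group as its argument, which left 26112 genes holding from 99.96% to 99.98% of the counts of each library. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with 1 coefficient per group over all 9 libraries, by robust quasi-likelihood. The 3 comparisons were ossro1c with WT, osdreb2b with WT, and osdreb2b with ossro1c. Adjusted p-values are Benjamini-Hochberg values over the 26112 genes of each comparison, with a threshold of 0.05. Levels are given as TMM-scaled CPM (counts scaled to library size), as mean ± SD with n = 3, and changes as log2 fold changes with a standard error (SE). The SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, and so is approximate for large changes. For single genes of the study, a two-sided exact permutation test of log2 CPM was added; 3 libraries against 3 cannot give a p below 0.1.

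Genes lower, or higher, in both mutants had to pass the threshold in the same direction in both comparisons with WT. As both comparisons share the WT libraries, their overlap and correlation were set beside 20 simulations in which no gene differed between groups and the WT libraries were shared. The WT group could not be split into separate sets of 2 libraries, so part of the excess in overlap may come from the shared controls.

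Before the data were examined, 14 gene lists with 194 members were fixed by locus identifier, together with the rule for the genes to be named. The pairs of locus and name come from knowledge of the rice genome and not from the count table, which holds no names. The lists cover study genes, DREB1/CBF and cold regulators, dehydrins with LEA proteins and osmoprotectants, abscisic acid, jasmonate, heat shock proteins and factors, reactive oxygen enzymes, photosynthesis, chlorophyll synthesis, chlorophyll breakdown and senescence, the circadian clock, defence and phytoalexins, root markers, and meristem and cell division. The last 2 lists stand for other cell types that a shoot sample could hold. Names were checked against a rice reference gene table (assembly ASM3414082v1), in which 132 of the names occur, 8 aliases having been added after that table was seen. Of these, 129 lie on the chromosome that the locus identifier gives, 126 of them within 1 Mb of the position interpolated from the identifiers (median distance 0.033 Mb). The other 3 lie only on another chromosome and were left out. Another 62 names, OsSRO1c among them, do not occur in the table and could not be checked. One further listed locus is missing from the count table, which left 190 members in use. Families defined by product names were fixed too but not used, since the files used here pair no locus with a product name.

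Lists with at least 5 tested members were tested with limma 3.58.1 (camera on log2 CPM with a prior count of 2) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. List p-values were adjusted by Benjamini-Hochberg over the lists of each comparison. Changed members were counted over all genes tested and adjusted over the list alone.

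Named genes followed the rule fixed beforehand. It takes the 5 study genes; the 8 highest and 8 lowest changes per comparison among genes past the threshold with a symbol in the reference table, a mean of at least 5 CPM in the higher group and no overlap between the groups; up to 3 members per list with the smallest adjusted p; and up to 2 well-known members that did not pass. For genes lower or higher in both mutants it takes the 10 with the most extreme mean of both changes under the same conditions. There the 5 CPM had to be met in WT for falls and in both mutant groups for rises. The reference table pairs symbols with listed loci only through the name check, so these extremes come from the lists and are not the extremes of all genes.

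The alternatives were size factors of the DESeq2 kind (RLE) in edgeR, upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter at 1 CPM in 3 libraries, quasi-likelihood without the robust option, a fit per comparison on its own 6 libraries, a size threshold of 1 on the log2 scale, an adjusted p threshold of 0.01, a replicate block, and leaving out each library in turn. Raw library totals, and lists restricted to members whose names were found in the reference table, were added after seeing the data.

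The method was tested on simulated data. For ossro1c against WT with 24453 genes, 19% of 100 genes changed by 0.5 on the log2 scale were recovered and 77% of 100 genes changed by 1, with 4 false calls among 100. No other genes were changed in this comparison, whereas 60.9% of tested genes passed in the data. Few changed genes make the Benjamini-Hochberg cutoff stricter, so these shares are not the recovery rates of the real comparisons. For osdreb2b against WT, the photosynthesis list shifted by 1 on the log2 scale was called. For ossro1c against WT, where single genes were changed but no list was shifted as a whole, 0 lists were called. Genes were simulated independently of each other. The simulation therefore cannot show how often lists are called wrongly when their genes move together, as in photosynthesis with an estimated correlation of 0.92. The biological coefficient of variation was 12.8% in WT, 25.3% in ossro1c and 16.3% in osdreb2b libraries. Library totals limit only genes of low count: for a single library, the smallest detectable level is set by a floor of 3 counts.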

Results

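The data are counts per locus from 9 RNA-seq libraries of rice shoots held at 4 °C for 2 d, with 3 libraries each of WT, ossro1c and osdreb2b plants. Totals were 64681976, 62942994 and 64783631 counts for WT replicates 1 to 3, 58398026, 67792790 and 69336224 for ossro1c, and 67192793, 61157501 and 67376150 for osdreb2b. Between 28026 and 29383 loci were detected per library. The first principal component, with 50.9% of the variance, separated WT from both mutant groups, and the next, with 27.8%, separated the mutant groups from each other. Replicate 3 of ossro1c stood apart from replicates 1 and 2 on the next component, which held 4.83%. Spearman correlations between libraries were 0.980 to 0.990 within groups and 0.906 to 0.943 between groups.

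The design text names OsSRO1c and OsDREB2B as partners of a complex, and genes lower in both mutants as its candidates. OsSRO1c is a member of the plant SRO family, proteins with a domain related to poly(ADP-ribose) polymerases, and OsDREB2B is an AP2/ERF transcription factor of the DREB2 class. Each transcript was compared between groups first, as a check of the genotype labels. OsSRO1c (LOC_Os03g12820, chromosome 3) stood at 2049 ± 27.4 CPM in WT (SD, n = 3), at 415 ± 36.2 CPM in libraries labelled ossro1c and at 134 ± 4.29 CPM in libraries labelled osdreb2b. It was therefore lowest under the label of the other mutant, at 6.52% of WT against 20.3% under its own label. OsDREB2B (LOC_Os05g27930, chromosome 5) stood at 169 ± 3.42 CPM in WT, 68.8 ± 9.96 CPM under the ossro1c label and 311 ± 10.3 CPM under the osdreb2b label, which is 40.7% and 183.6% of WT. Between the mutant labels, OsSRO1c was lower by a log2 fold change of -1.63 (SE 0.07, adjusted p = 6.7e-10, edgeR) and OsDREB2B higher by 2.18 (SE 0.10, adjusted p = 5.4e-10) in libraries labelled osdreb2b. In each of the 6 mutant libraries, the gene that the label names was above its level in every library of the other mutant label. The labels are used below as given, so that each direction stated for a mutant belongs to the libraries carrying that label.

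**Figure D1:**
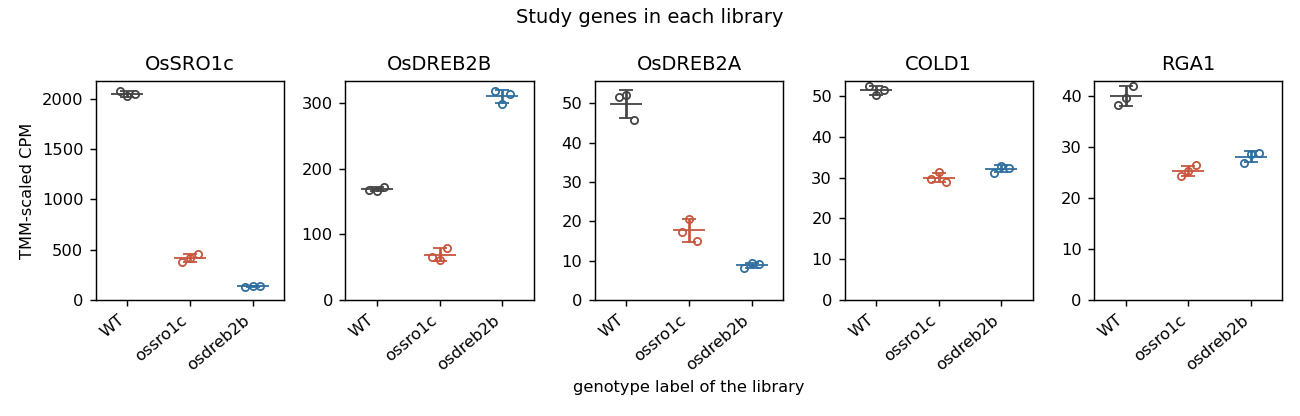
TMM-scaled CPM of the 5 study genes by genotype label; circles are the 3 libraries of each group, horizontal bars their mean and error bars the SD, with a separate axis from 0 for each gene. COLD1 and RGA1 were lower than WT under both mutant labels, and OsDREB2B was above WT (183.6%) in the libraries labelled osdreb2b.

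COLD1 (LOC_Os04g51180, chromosome 4), a membrane protein of cold sensing, is named in the title of the series as a gene that the complex regulates. Its transcript was lower than in WT under both mutant labels, whose targeted genes are in doubt as described. COLD1 fell from 51.4 ± 1.14 CPM in WT to 30.04 ± 1.18 CPM under the ossro1c label (log2 fold change -0.78, SE 0.08, adjusted p = 1.2e-06) and to 32.2 ± 0.817 CPM under the osdreb2b label (-0.68, SE 0.08, adjusted p = 4.5e-06; n = 3 each, edgeR quasi-likelihood). All 3 libraries of each mutant label lay below all 3 of WT, for which the exact permutation test gives p = 0.1, the smallest that 3 libraries against 3 allow. Between the mutant labels COLD1 differed by 0.10 (SE 0.08, adjusted p = 0.32; exact permutation p = 0.2), which did not pass the threshold. Both falls of COLD1 from WT were smaller under raw library totals, which raise log2 changes by about 0.32 under the ossro1c label and 0.14 under the osdreb2b label. RGA1 (LOC_Os05g26890), the G protein alpha subunit that COLD1 is known to act with, fell by 0.66 on the log2 scale under the ossro1c label and by 0.51 under the osdreb2b label. OsDREB2A (LOC_Os01g07120), the closest paralog of OsDREB2B, fell 2.82-fold and 5.66-fold. Of the 5 study genes, 5 were lower under the ossro1c label (camera adjusted p = 0.0072, 0.26 with an estimated correlation). Under the osdreb2b label 4 were lower and 1, OsDREB2B, was higher (adjusted p = 0.0501; 0.026 to 0.078 over the alternatives at the preset correlation). The list was built around genes that the series names, with OsDREB2A added as a paralog, so it is not independent evidence of its own direction.

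Compared with WT, transcripts of heat shock proteins and factors and of clock genes were lower as groups in libraries labelled ossro1c, and those of DREB1/CBF and cold regulators and of jasmonate genes higher. With an estimated correlation the adjusted p was 0.29 for heat shock genes and 0.63 for each of the other lists. HSP24.1 (LOC_Os02g52150) fell 68.5-fold, from 301 ± 7.06 to 4.39 ± 1.32 CPM (log2 -6.10, SE 0.17, n = 3), and HSP82A (LOC_Os08g39140), an HSP90 chaperone, fell 53.9-fold, from 599 ± 2.40 to 11.1 ± 0.722 CPM. OsDREB1B (LOC_Os09g35010), a DREB1/CBF factor of the cold response, rose from 3.30 ± 0.147 to 219.9 ± 56.9 CPM, a 66.5-fold change. In all, 15892 of 26112 genes (60.9%) passed the threshold, 7685 higher and 8207 lower, and 4591 and 4356 of them changed by at least 1 on the log2 scale.

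Of the heat shock list, 11 of 17 tested members were lower and 2 higher (median log2 -3.26, camera adjusted p = 0.0028; adjusted p = 0.29 with an estimated correlation). Besides HSP24.1 and HSP82A, HSP18.0 (LOC_Os01g08860) fell by 4.25 on the log2 scale, HSP17.4 (LOC_Os03g15960) by 4.23, the disaggregase HSP101 (LOC_Os05g44340) by 3.26, and the heat shock factor HSFB2c (LOC_Os09g35790) by 3.82. The small heat shock protein locus LOC_Os03g16020, whose name was not in the reference table, fell by 7.10. HSP70 (LOC_Os03g60620) was at 83.7 ± 4.13 CPM in WT and 92.5 ± 4.72 CPM in ossro1c, which did not pass the threshold (adjusted p = 0.17), though it did under upper-quartile scaling, raw totals, a filter at 1 CPM and a fit on the 6 libraries alone.

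Among DREB1/CBF and cold regulators, 12 of 23 were higher and 5 lower (median 0.35, adjusted p = 0.041; adjusted p = 0.63 with an estimated correlation). This call was lost with the replicate block (adjusted p = 0.062) and without ossro1c replicate 3 (adjusted p = 0.064; 0.0094 to 0.064 over the alternatives at the preset correlation). The median was 0.67 under raw totals, 1.10 for members found in the reference table, and 0.56 to 0.62 when WT replicate 1 or 2, ossro1c replicate 1 or any osdreb2b library was left out. OsDREB1C (LOC_Os06g03670) rose by 5.66, OsDREB1G (LOC_Os02g45450) by 4.76 and OsWRKY76 (LOC_Os09g25060), a WRKY repressor, by 4.14. OsCNGC9 (LOC_Os09g38580), a cyclic nucleotide-gated channel, was at 64.3 ± 1.30 and 57.6 ± 0.932 CPM and did not pass (adjusted p = 0.068), though it did without ossro1c replicate 3 (log2 -0.15). Of the jasmonate genes, 10 of 16 were higher and 2 lower (median 0.60, 0.92 under raw totals; adjusted p = 0.0083; adjusted p = 0.63 with an estimated correlation). OsJAZ9 (LOC_Os03g08310), a JAZ repressor of jasmonate signalling, rose by 2.14, OsJAZ6 (LOC_Os03g28940) by 1.10, and OsJAR2 (LOC_Os01g12160), of the family that joins jasmonate to amino acids, by 2.94. OsJAZ12 (LOC_Os10g25290), at 296 ± 6.29 CPM in WT and 304 ± 46.6 CPM in ossro1c, did not pass (adjusted p = 0.77), except under raw library totals.

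Clock genes were lower under the ossro1c label in 8 of 9 cases and higher in 0 (median -0.65, -0.33 under raw totals; adjusted p = 0.0083, and 0.63 with an estimated correlation). Under raw totals PRR1 (LOC_Os02g40510), GI (LOC_Os01g08700) and LUX (LOC_Os01g74020), named here after their values were seen, did not pass (adjusted p = 0.17, 0.29 and 0.78). LUX did not pass under upper-quartile scaling or on the 6 libraries alone either. PRR59 (LOC_Os11g05930) fell 2.82-fold, PRR95 (LOC_Os09g36220) by 1.43 on the log2 scale and PRR37 (LOC_Os07g49460) by 1.04. The remaining lists did not pass by camera. By fry, which does not compare a list with other genes, abscisic acid (adjusted p = 0.00017), defence (2.8e-05) and chlorophyll breakdown genes (6.4e-05) passed as well. Abscisic acid genes went both ways, with 8 of 21 higher and 9 lower (median -0.23, -0.07 under upper-quartile scaling, 0.09 under raw totals and -0.37 to -0.13 with 1 library left out; adjusted p = 0.96). The catabolic enzyme gene OsABA8ox1 (LOC_Os02g47470) rose 22.2-fold and the synthesis gene OsNCED4 (LOC_Os07g05940) 15.7-fold, while the phosphatase gene OsPP2C09 (LOC_Os01g62760) fell by 1.03 on the log2 scale. Dehydrins, LEA proteins and osmoprotectants had 2 of 14 higher and 6 lower (median -0.43, -0.27 under upper-quartile scaling and -0.11 under raw totals; adjusted p = 0.30). Of these the dehydrin gene RAB16A (LOC_Os11g26790) fell by 2.83, the galactinol synthase gene OsGolS2 (LOC_Os07g48830) fell by 1.42, and the trehalose phosphatase gene OsTPP1 (LOC_Os02g44230) rose 6.84-fold. Defence genes had 4 of 14 higher and 8 lower (median -1.32, -3.11 for members found in the reference table and -2.07 to -0.56 with 1 library left out; adjusted p = 0.30), with the chitinase gene CHT1 (LOC_Os06g51060) lower by a log2 change of -3.11 and the phenylalanine ammonia lyase gene PAL5 (LOC_Os04g43800) higher by 2.16.

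Photosynthesis genes were mixed under the ossro1c label, with 5 of 17 higher and 8 lower (median -0.21, -0.05 under upper-quartile scaling, 0.11 under raw totals and -0.41 to -0.13 with 1 library left out; adjusted p = 0.30). CAB1R (LOC_Os09g17740), a chlorophyll a/b binding protein gene, fell by 2.47 and LHCA4 (LOC_Os08g33820), of the photosystem I antenna, by 1.18, while PSBS1 (LOC_Os01g64960), of photoprotection, rose by 1.69. CAB2R (LOC_Os01g41710) was at 103.8 ± 4.79 CPM in WT and 105 ± 29.7 CPM in ossro1c (log2 0.02), but at -0.23 and past the threshold without ossro1c replicate 3. Chlorophyll synthesis genes had 5 of 9 higher and 3 lower (median 0.18, 0.34 under upper-quartile scaling and 0.502 under raw totals; mean -0.03, adjusted p = 0.75). PORB (LOC_Os10g35370), a protochlorophyllide reductase gene, fell by 1.69. In the same libraries the root marker Lsi1 (LOC_Os02g51110), a silicon transporter gene, rose from 2.42 ± 0.347 to 17.5 ± 2.04 CPM, with 1 of 3 root markers higher and 0 lower, a list too short for a set test. Cell division genes had 2 of 5 higher and 0 lower (median 0.05, 0.21 under upper-quartile scaling, 0.36 under raw totals and -0.09 to 0.16 with 1 library left out; adjusted p = 0.57). Adjusted over the list alone, the counts of changed members in this comparison were those given for each of the 14 lists.

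With raw library totals in place of TMM, the median change of all genes under the ossro1c label moved to 0.32 on the log2 scale and the split to 10264 higher and 5971 lower (63.2% higher, against 48.4%); with upper-quartile scaling the median was 0.16. For osdreb2b against WT the medians were 0.17 and 0.15.

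In libraries labelled osdreb2b, photosynthesis and chlorophyll synthesis genes were higher as groups than in WT, and heat shock, jasmonate, dehydrin and defence genes were lower. With an estimated correlation the adjusted p was 0.039 for chlorophyll synthesis, 0.33 for photosynthesis, 0.25 for heat shock, 0.52 for jasmonate, 0.20 for dehydrin and 0.26 for defence genes. PORA (LOC_Os04g58200), a protochlorophyllide reductase gene, rose 33.4-fold, from 22.5 ± 0.176 to 752 ± 22.2 CPM (log2 5.06, SE 0.17, n = 3). CAB2R rose 24.7-fold, to 2563 ± 201 CPM, and LHCB2 (LOC_Os03g39610), of the photosystem II antenna, rose 7.55-fold, from 577 ± 29.1 to 4355 ± 241 CPM. OsLEA3 (LOC_Os05g46480), a late embryogenesis abundant protein gene, fell 42.8-fold, from 7.76 ± 0.884 to 0.177 ± 0.104 CPM. The threshold was passed by 15562 genes (59.6%), 7820 higher and 7742 lower, of which 4522 and 4251 changed by at least 1 on the log2 scale.

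All 17 tested photosynthesis genes were higher under the osdreb2b label (median 2.11, adjusted p = 2e-08; adjusted p = 0.33 with an estimated correlation), among them LHCA4 at 2.25 and LHCB3 (LOC_Os07g37550) at 2.15. All 9 chlorophyll synthesis genes were higher too (median 1.47, adjusted p = 2.5e-05), and this call held with an estimated correlation (adjusted p = 0.039). The estimate for chlorophyll synthesis was -0.017, so the test made no allowance for genes that move together. Of these CRD1 (LOC_Os01g17170), a cyclase subunit gene, rose by 1.91 and PORB by 1.83. In the same libraries CDKB2;1 (LOC_Os08g40170), a kinase gene of dividing cells, rose 3.64-fold to 27.3 ± 2.44 CPM, with 3 of 5 cell division genes higher and 0 lower (median 0.90, adjusted p = 0.42), and Lsi1 rose 4.22-fold, with 1 of 3 root markers higher and 0 lower. The 15 loci with the most counts took from 7.27% to 7.63% of counts in these libraries and from 4.26% to 5.50% in the other 6.

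The heat shock list had 10 of 17 members lower and 2 higher (median -1.60, adjusted p = 0.0028; adjusted p = 0.25 with an estimated correlation). HSP82A and HSP24.1 each fell by 5.08 on the log2 scale, HSP101 by 4.40, HSP17.4 by 3.44, and the locus LOC_Os03g16020 fell by 7.19. Dehydrins, LEA proteins and osmoprotectants had 10 of 14 lower and 1 higher (median -1.37, adjusted p = 0.0028; adjusted p = 0.20 with an estimated correlation). RAB16A fell 11.3-fold and OsTPP2 (LOC_Os10g40550) fell 7.40-fold, and OsTPP1 was the 1 that rose, 11.2-fold. Of the jasmonate genes 11 of 16 were lower and 2 higher (median -0.69, adjusted p = 0.015; adjusted p = 0.52 with an estimated correlation). OsJAZ9 and OsJAZ13 (LOC_Os10g25230) each fell by 3.30, OsJAZ11 (LOC_Os03g08320) by 2.95 and OsJAZ12 by 2.59. The 2 that were higher, named after their values were seen, were OsJAR2, 8.03-fold, and OsJAZ6, by 0.68 on the log2 scale.

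Defence genes had 10 of 14 lower and 2 higher (median -0.93, adjusted p = 0.0069; adjusted p = 0.26 with an estimated correlation), and did not pass when limited to members found in the reference table, where the median was lower still (-2.65, adjusted p = 0.054; 0.0024 to 0.054 over the alternatives at the preset correlation). WRKY70 (LOC_Os05g39720) fell by 4.63, CHT1 by 2.65 and PR4 (LOC_Os11g37970) by 2.24. Cold regulators were split, with 9 of 23 higher and 10 lower (median -0.16, 0.13 for members found in the reference table, -0.04 under upper-quartile scaling, -0.01 under raw totals and -0.02 to -0.003 when any 1 library other than ossro1c replicates 2 and 3 was left out; mean 0.24, adjusted p = 0.63). OsDREB1H (LOC_Os09g35020) rose 31.4-fold, OsDREB1B 27.0-fold and OsDREB1A (LOC_Os09g35030) 8.17-fold, whereas OsNAC6 (LOC_Os01g66120), a NAC factor of the stress response, fell 6.28-fold and OsMYB4 (LOC_Os04g43680) 5.19-fold. Abscisic acid genes had 8 of 21 higher and 9 lower (median -0.42, -0.83 for members found in the reference table; adjusted p = 0.45), with OsABA8ox1 higher 14.1-fold and OsPP2C06 (LOC_Os01g40094) lower 3.92-fold. Clock genes had 5 of 9 higher and 2 lower (median 0.37, 0.64 for members found in the reference table; adjusted p = 0.29), with LUX higher by 2.43 and PRR1 by 1.66. By fry all 13 lists tested passed, including the 7 that camera did not call. These were cold regulators (adjusted p = 0.0025), abscisic acid (0.014), clock (0.0025), cell division (0.0023), reactive oxygen (0.00085), chlorophyll breakdown (8.2e-05) and study genes (5.8e-08). Adjusted over the list alone, the clock list had 5 higher and 3 lower, and the counts of the other 13 lists were those given.

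**Figure D2:**
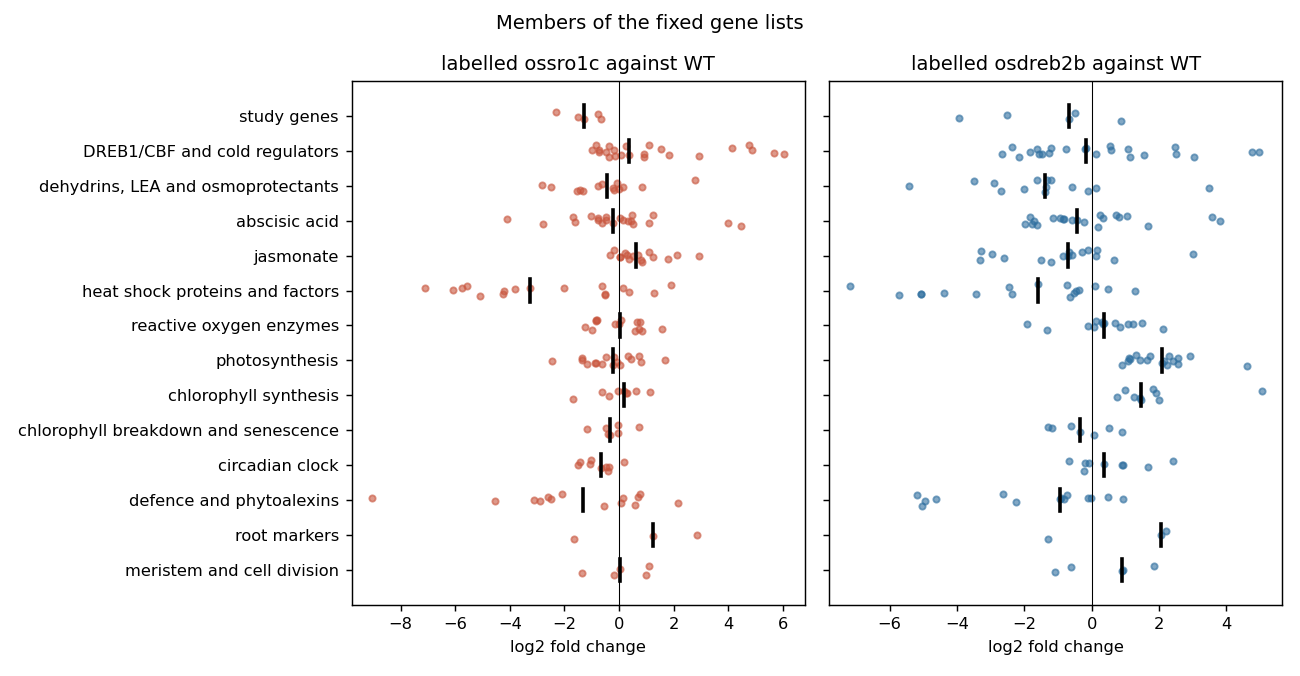
Log2 fold change against WT of each tested member of the 14 gene lists, for libraries labelled ossro1c (left) and osdreb2b (right); each point is a gene, each vertical bar the median of its list, and the defence gene near -9 on the left has counts of 0 in all ossro1c libraries, so its position depends on the fit. Photosynthesis genes have a median of -0.21 on the left (0.11 under raw totals) and 2.11 on the right, and heat shock genes are below 0 in median on both sides.

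The candidates named by the design text, genes lower in both mutants, numbered 5543 of 26112 tested genes. They were 67.5% of the genes lower under the ossro1c label and 71.6% of those lower under the osdreb2b label. COLD1 was among them at rank 4373 when ordered from the largest fall, with a mean log2 change of -0.73 against a median of -1.16 for the list. Its changes of -0.78 under the ossro1c label and -0.68 under the osdreb2b label were also smaller than the median absolute change of all tested genes, 0.81 and 0.79. Listed genes were ranked if they had a symbol in the reference table, at least 5 CPM in the higher groups and no overlap with WT. The largest falls in both in this ranking were those of HSP24.1, HSP82A, HSP17.4, HSP101, OsLEA3, RAB16A, HSFB2c, HSP18.0, CHT1 and OsDREB2A in that order, with a mean log2 change of -5.59 for HSP24.1. Genes absent from the reference table were not ranked, and of these LOC_Os03g16020 fell further, at -7.10 under the ossro1c label and -7.19 under the osdreb2b label. OsSRO1c, which a mutant label names, and WRKY70 were also absent from that table. Each fell by more than OsDREB2A under both labels. Higher in both were 5156 genes. The largest rises in the same ranking were those of OsDREB1B, OsABA8ox1, OsWRKY76, OsTPP1, Lsi1, OsDREB1A, OsRBOHB (LOC_Os01g25820), CHLH (LOC_Os03g20700), OsPP2C08 (LOC_Os01g46760) and SODCP (LOC_Os08g44770). Their means ran from 5.41 to 0.99 on the log2 scale. OsJAR2 and PSBS1, absent from the reference table, were not ranked, and each rose by more than OsRBOHB under both labels. OsDREB1H (3.72 CPM under the ossro1c label) and OsDREB1C (4.61 CPM under the osdreb2b label) missed the 5 CPM. Both rose by more than OsPP2C08 under both labels. Of 174 tested members of the lists, 45 were lower in both, 37 higher in both and 39 changed in opposite directions.

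Independent lists of these sizes would share 2433 lower and 2302 higher genes. Simulated groups without any change shared at most 1 lower gene and 0 higher genes. With no gene changed, hardly any could pass in either comparison. The simulated overlaps therefore cannot show how much the shared WT libraries add to lists of the observed sizes. Across genes, which are not independent replicates, both log2 fold changes had a Pearson r of 0.694 and a Spearman rho of 0.665. Groups without any change but with shared WT libraries gave a mean r of 0.518 over 20 simulations (0.486 to 0.545), with a covariance of 0.140 against 2.11 in the data. Noise in the shared WT libraries is already part of the simulated covariance, which falls short of the value in the data. Anything common to all WT libraries, such as a batch, would add to the excess and cannot be told apart from genotype. Changes of at least 1 on the log2 scale in both comparisons were found for 2512 lower and 2645 higher genes.

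**Figure D3:**
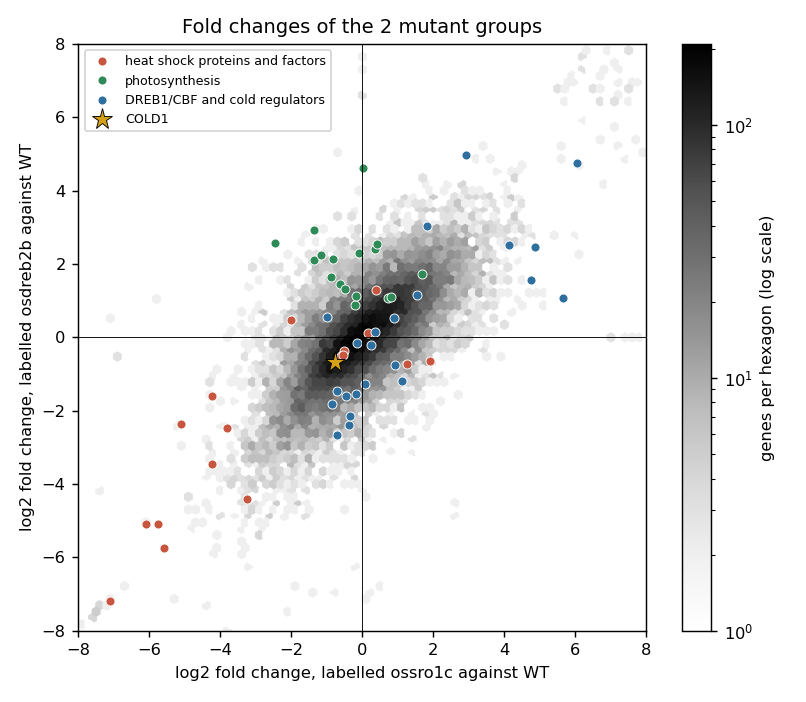
Log2 fold change against WT of libraries labelled osdreb2b (vertical) and ossro1c (horizontal) for 25854 of the 26112 tested genes, the other 258 lying beyond the axes; shading counts genes per hexagon on a log scale, and coloured points are members of 3 gene lists and COLD1. Both axes share the WT libraries, r was 0.694 across genes, and photosynthesis genes lie above 0 on the vertical axis.

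The direct comparison of both mutant labels asks where the mutants differ. Photosynthesis, chlorophyll synthesis and clock genes were higher under the osdreb2b label, and jasmonate genes and DREB1/CBF and cold regulators were higher under the ossro1c label as groups. With an estimated correlation the adjusted p was 0.042 for chlorophyll synthesis, 0.29 for photosynthesis and for the clock, and 0.17 for jasmonate genes and for cold regulators. OsDREB1A and OsDREB1H, named here after their values were seen, were the 2 cold regulators that went the other way, higher under the osdreb2b label by 1.20 and 2.04 on the log2 scale. PORA was 51.3-fold higher (752 against 14.6 ± 4.42 CPM, n = 3) and CAB1R 33.1-fold higher (1957 ± 124 against 59.0 ± 14.5 CPM) in libraries labelled osdreb2b. OsJAZ9 was 43.2-fold lower there (2.35 ± 0.604 against 101 ± 18.2 CPM) and OsDREB1C 23.9-fold lower (4.61 ± 0.278 against 110.2 ± 23.4 CPM). The threshold was passed by 12147 genes (46.5%), 5974 higher and 6173 lower under the osdreb2b label; with raw library totals the split was 4398 higher and 8054 lower (35.3% higher, against 49.2%) and the median moved to -0.20.

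Of the photosynthesis genes 16 of 17 were higher under the osdreb2b label and 0 lower (median 2.14, adjusted p = 1.8e-10; adjusted p = 0.29 with an estimated correlation), with CAB2R at 4.61 and LHCB2 at 4.28. Chlorophyll synthesis genes had 8 of 9 higher and 1 lower (median 1.37, adjusted p = 1.3e-05), a call that held with an estimated correlation of -0.017 (adjusted p = 0.042). PORB was higher by 3.52 and YGL1 (LOC_Os05g28200), the chlorophyll synthase gene, named after its values were seen, was the 1 that was lower (log2 -0.38). CDKB2;1 was higher by 1.82 in the same libraries, the 1 of 5 cell division genes that changed (median -0.06, -0.11 under upper-quartile scaling, -0.24 under raw totals and -0.21 to 0.04 with 1 library left out; adjusted p = 0.96), and Lsi1 was lower (log2 -0.78), the 1 of 3 root markers that changed. All 9 clock genes were higher (median 0.84, adjusted p = 1e-05; adjusted p = 0.29 with an estimated correlation), with LUX at 2.80 and PRR95 at 2.37. GI was higher by 0.21 (0.14 without ossro1c replicate 3) but did not pass under another scaling, with DESeq2, with a filter at 1 CPM, on the 6 libraries alone, or without any of the WT libraries, osdreb2b replicate 2 or osdreb2b replicate 3.

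Of the jasmonate genes 15 of 16 were lower under the osdreb2b label and 0 higher (median -0.93, adjusted p = 6.1e-08; adjusted p = 0.17 with an estimated correlation), with OsJAZ13 at -4.55, OsJAZ11 at -3.17, OsJAZ10 (LOC_Os03g08330) at -2.99 and OsJAZ12 at -2.63. Cold regulators had 17 of 23 lower and 2 higher (median -1.30, adjusted p = 3.3e-06; adjusted p = 0.17 with an estimated correlation), with OsDREB1G at -3.20 and OsWRKY71 (LOC_Os02g08440) at -2.30. Dehydrins, LEA proteins and osmoprotectants had 10 of 14 lower and 1 higher (median -0.57, adjusted p = 0.0076; adjusted p = 0.17 with an estimated correlation), with OsTPP2 at -2.90. Heat shock genes had 7 of 17 higher and 2 lower (median 0.14, -0.05 under raw totals and 0.08 to 0.62 with 1 library left out; adjusted p = 0.14), with HSP18.0 higher by 2.65. Limited to members found in the reference table, the list passed with a median of 0.85 (adjusted p = 0.0090; 0.0090 to 0.21 over the alternatives at the preset correlation). Abscisic acid genes had 5 of 21 higher and 11 lower (median -0.35, -0.53 under raw totals; mean 0.01, adjusted p = 0.070), and passed with DESeq2 (adjusted p = 0.047) and when limited to members found in the reference table (0.0090 to 0.14 over the alternatives at the preset correlation). OsNCED4 was lower by a log2 change of -4.54 and OsZEP1 (LOC_Os04g37619), the zeaxanthin epoxidase gene, higher by 2.44. Defence genes had 2 of 14 higher and 7 lower (median -0.38, and -0.81 to -0.28 with 1 library left out; adjusted p = 0.056), a set test that passed in some alternatives (0.015 to 0.37 at the preset correlation), among them those without each of the WT libraries. The study genes had 1 of 5 higher and 2 lower (median 0.10, 0.05 under upper-quartile scaling and -0.08 under raw totals; mean -0.04, adjusted p = 0.96). By fry, heat shock (adjusted p = 0.00083), abscisic acid (3.5e-05), defence (3.5e-05) and reactive oxygen genes (0.00018) passed as well. Adjusted over the list alone, cold regulators had 2 higher and 18 lower, heat shock genes 8 and 2, and defence genes 2 and 9, with the other lists as given.

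Genes that were higher under 1 mutant label and lower under the other were fewer than shared ones, at 506 higher in ossro1c and lower in osdreb2b and 872 lower in ossro1c and higher in osdreb2b. CAB1R, LHCB2, PORA and PORB were of the latter kind, where the fall of PORA under the ossro1c label (log2 -0.62) did not pass under raw library totals (-0.31). OsJAZ9, OsJAZ10, OsJAZ13 and PAL5 were of the former.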

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

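The count of sample splits was chosen before the result was seen, and the tests of label swap, edited transcripts, scaling, repeated sequencing, single libraries and harvest hour were chosen after. Groups of 3 libraries were not searched for outlying samples. By their separate comparisons with WT, 506 genes were higher in ossro1c and lower in osdreb2b, and 872 were lower in ossro1c and higher in osdreb2b. The other differences listed here between libraries labelled osdreb2b and ossro1c were tested directly with edgeR or camera. The threshold was passed by 12147 genes. OsSRO1c differed by a log2 fold change of -1.63, OsDREB2B by 2.18 and OsDREB2A by -1.01. The list medians that differed were 2.14 for photosynthesis, 1.37 for chlorophyll synthesis, 0.84 for the clock, -1.30 for DREB1/CBF and cold regulators, -0.93 for jasmonate and -0.57 for dehydrins, LEA proteins and osmoprotectants. With an estimated correlation, the chlorophyll synthesis call was the only one of these 6 that held. Its estimate was -0.017, against 0.92 for photosynthesis and 0.86 for the clock. For chlorophyll synthesis the test therefore made no allowance for genes that move together.

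The gene named by each mutant label was more abundant under that label than under the other. A swap of both labels stays open: the gene named by the label was above every library of the other label in 6 of 6 mutant libraries, but this count restates the pattern and cannot support a swap. Correct labels with edited transcripts that are still transcribed and counted stay open as well, since OsSRO1c remained at 20.3% of WT under its own label, and read sequences, which would show an edit, were not analysed here. Under that explanation OsDREB2B would be 183.6% of WT in its own mutant and OsSRO1c 6.52% of WT in the osdreb2b mutant. Under a swap OsDREB2B would remain at 40.7% of WT in its own mutant, and OsSRO1c would be 20.3% of WT in the osdreb2b mutant. A swap would therefore also leave a targeted transcript in the counts. Genes lower or higher in both mutants do not depend on which mutant is which, whereas every direction given for a single mutant does.

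More than 40% of tested genes passed the threshold in each comparison. Library scaling as the whole cause is argued against, since the lowest share over 4 scalings and 3 comparisons was 46.4%. Repeated sequencing of 1 library per group is argued against as well: the median squared difference between libraries of a group was at least 6.07 times that of sampling noise. For the 6 libraries of each comparison fitted alone, 1 of the 10 splits, the real one, reached the counts of 15460 for ossro1c against WT, 16716 for osdreb2b against WT and 11304 for osdreb2b against ossro1c. The highest other split gave 0 by edgeR, with 158, 97 and 431 genes at an unadjusted p under 0.05. Every other split mixes libraries of both groups, so the group difference adds to the spread within each side and lowers these counts. In addition, 10 splits are too few for a share under 0.05. Genotype, and anything else shared by the 3 libraries of a group such as growth, harvest or library batch, stay open, because the labels give no batch.

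Photosynthesis and chlorophyll synthesis genes were higher in libraries labelled osdreb2b than in those labelled ossro1c. Neither scaling nor 1 library accounts for it: the median of the photosynthesis genes was at least 1.96 over 4 scalings and at least 2.05 when any of the 6 libraries was left out. A different hour of harvest could also move these genes, which follow the day in rice leaves. For a shift, dawn and dusk genes were predicted to move in opposite directions, with at most 6 of the 9 clock genes higher. Without a shift, few clock genes were predicted to differ. In the clock list 9 of 9 genes were higher, so neither prediction was met. The list was not balanced between genes of dawn and of dusk, so this count speaks neither for nor against a shift in hour. The hour is not in the labels and clock rhythms at 4 °C are not known here, so a different hour cannot be told apart from genotype. A difference between the genotypes, whichever label each carries, stays open and untested.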

How the results depend on the processing

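Raw library totals and lists limited to members found in the reference table were chosen after seeing the data; the other alternatives were fixed before. Counts were labelled the same when within a fixed ratio of the main count. The correlation was judged by the SD of its values with 1 library left out, and single genes and lists by direction and side of the threshold. A change of sign was labelled the same where neither value passed. OsJAZ12 in ossro1c, at -0.10 to 0.11 with 1 library left out, and the photosynthesis median in ossro1c, at 0.11 under raw totals against -0.21, were such cases. By these labels, 481 of the recomputed counts and main results were the same, 25 moved, 3 became weaker and 0 reversed. A count labelled the same can still differ, as with 10264 genes higher in ossro1c than in WT under raw totals against 7685 under TMM. Requiring at least 1 on the log2 scale leaves fewer genes by construction: 8947 changed in ossro1c against WT (4591 higher, 4356 lower), 8773 in osdreb2b against WT (4522 and 4251), 5446 in osdreb2b against ossro1c (2535 and 2911), 2512 lower in both and 2645 higher in both. COLD1 (-0.78 and -0.68) and OsDREB2B in osdreb2b (0.88) lie below that size, and the lists called fall to 2 for ossro1c and 3 between the mutants. With an estimated inter-gene correlation 0 lists were called for ossro1c, 1 for osdreb2b and 1 between the mutants, chlorophyll synthesis being the 1 in both. The correlation of fold changes was 0.627 with DESeq2, 0.619 without a filter and 0.743 on the 6 libraries of each comparison, and 0.655 to 0.706 when 1 library was left out; the cause was not tested. Leaving out 1 library gave 14659 to 16452 genes for ossro1c, 14271 to 16962 for osdreb2b and 10713 to 13097 between the mutants, with 5038 to 6099 lower in both and COLD1 at -0.81 to -0.75 in ossro1c against WT. Scaling moved COLD1 further. TMM factors ran from 0.89 to 0.90 in WT and from 1.09 to 1.14 in ossro1c. Relative to TMM, raw totals raise log2 changes against WT by about 0.32 in ossro1c and 0.14 in osdreb2b, and upper-quartile scaling by 0.16 and 0.11. The falls of COLD1 were smaller there but still passed. Without ossro1c replicate 3, which stood apart, 16452, 16962 and 13097 genes passed, including 95.0%, 99.6% and 93.7% of the original calls and 0 in the opposite direction. Of the named genes, 4140 recomputed values were the same, 118 became weaker, 25 stronger and 1 reversed: CAB2R in ossro1c, from 0.02 to -0.23 without ossro1c replicate 3 (-0.23 to 0.16 over the libraries left out). Of the lists, 834 values were the same, 28 weaker and 23 stronger. Replicate numbers do not pair the libraries, with correlations of residuals from -0.009 to 0.022 across groups; with a replicate block 15666, 15264 and 11821 genes passed, and cold regulators in ossro1c did not pass as a set (adjusted p = 0.062, range over the alternatives 0.0094 to 0.064 at the preset correlation). Depth limits only genes near the floor of 3 counts per library.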

Other observations

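Neither reactive oxygen enzymes nor chlorophyll breakdown genes passed as a list by camera in the 3 comparisons. By fry, which does not compare a list with other genes, reactive oxygen enzymes passed in osdreb2b against WT (adjusted p = 0.00085) and against ossro1c (0.00018), and chlorophyll breakdown genes passed in ossro1c (6.4e-05) and osdreb2b (8.2e-05) against WT. Of 14 reactive oxygen enzyme genes, 6 were higher and 6 lower in libraries labelled ossro1c than in WT (median log2 0.03, 0.19 under upper-quartile scaling, 0.35 under raw totals and -0.14 to 0.15 with 1 library left out; camera direction down, adjusted p = 0.96), and 8 were higher and 2 lower in those labelled osdreb2b (median 0.36, adjusted p = 0.081; 0.048 with DESeq2, the lowest of a range up to 0.10 over the alternatives). OsCATA (LOC_Os02g02400), a catalase gene, fell from 277 ± 8.97 CPM in WT to 139.5 ± 9.45 CPM in ossro1c (n = 3) and rose to 1212 ± 17.2 CPM in osdreb2b, an 8.68-fold difference between the mutant labels. OsGR2 (LOC_Os02g56850), a glutathione reductase gene, fell by 1.24 on the log2 scale in ossro1c and by 1.91 in osdreb2b. OsRBOHB, an NADPH oxidase gene, rose 2.98-fold and 2.82-fold, and SODCP, a plastid superoxide dismutase gene, 1.69-fold and 2.33-fold. Between the mutant labels 7 of the 14 were higher and 3 lower in osdreb2b (median 0.27, 0.09 under raw totals; adjusted p = 0.14), a list that passed without ossro1c replicate 3 (adjusted p = 0.046; up to 0.23 over the alternatives).

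Of 7 genes of chlorophyll breakdown and senescence, 1 was higher and 4 lower in ossro1c (median -0.33, -0.17 under upper-quartile scaling and -0.01 under raw totals; adjusted p = 0.30), 2 were higher and 4 lower in osdreb2b (median -0.36, -0.22 under raw totals; adjusted p = 0.45), and 2 were higher and 2 lower in osdreb2b than in ossro1c (median 0.04, -0.001 under upper-quartile scaling, -0.14 under raw totals and -0.02 to 0.07 with 1 library left out; adjusted p = 0.99). PAO (LOC_Os03g05310), the pheophorbide a oxygenase gene, fell by 1.17 and 1.31 on the log2 scale in ossro1c and osdreb2b. SGR (LOC_Os09g36200), the stay-green gene, fell by 1.18 in osdreb2b, and its fall in ossro1c did not pass under raw totals (adjusted p = 0.87). OsNAP (LOC_Os03g21060), a NAC factor of leaf senescence, rose 1.66-fold in ossro1c and fell 1.54-fold in osdreb2b.

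Some loci were counted in whole groups and stood at or under the floor in others. With at least 100 counts in every library on one side and at most 3 in every library on the other, 8 loci were counted in WT alone, 5 in ossro1c alone, 5 in osdreb2b alone, 6 in both mutants but not in WT, 1 in WT and ossro1c but not in osdreb2b, and 1 in WT and osdreb2b but not in ossro1c. The most abundant of the WT loci, LOC_Os09g32370, had 1397 to 1547 counts per library, and LOC_Os03g02470, of the loci counted in both mutants, had 1009 to 5252. Both were named after their values were seen.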
